A study of Branchiostoma lanceolatum with 8 samples.

How the data were processed

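Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open chromatin, in ectodermal explants of the amphioxus Branchiostoma lanceolatum. Per the labels, 8 libraries were made, 2 for each of 4 groups: control explants and explants treated with human recombinant Activin at 50 ng per mL, each at 11 and at 19 hours post fertilization (hpf). Nothing in the labels says whether the 2 libraries of a group came from separate batches of embryos.

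The authors deposited 1 list of differential regions per time point, with the scaffold, start, end, region name and a signed value for each region. Per the submitters' processing notes, BWA and DESeq2 were among the tools used by the authors, with no versions given. The genome build, the peak caller, the significance threshold, and whether peaks were called per library or on pooled libraries are not given in the sources used here. The signed column was read as the authors' log2 fold change between Activin and control libraries of one time point. This reading rests on the values: none is 0, and the smallest absolute value falls from 1.21 in the narrowest width quartile to 0.98 in the widest at 11 hpf, and from 1.56 to 1.44 at 19 hpf, as happens when fold changes are kept by a p-value and wider regions hold more reads. The base of the logarithm is not written in the lists and is taken from that tool's usual output. Which group is the numerator is not stated either, so "positive" and "negative" below repeat the deposited sign, and neither is called opened or closed by Activin.

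The lists hold no values per library, no read counts and no p-values. The depth of each library is therefore unknown, no test between libraries was made here, and each listed region rests on the authors' fit of 2 against 2 libraries. All tests below run over regions, which are not replicates. They describe the lists.

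The region names are numbers that increase along each scaffold without repeats (0 out of order in either list). They were taken as places in a wider ordered set of regions, with at least 111831 members at 11 hpf and 87262 at 19 hpf, the highest numbers listed. Scaffold lengths were not used here, so the span of a scaffold is the end of its last region in either list. Starts are given 1-based.

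Shares have exact 95% Clopper-Pearson intervals, which cover counting error only, and the share of positive regions was set against an even split by a two-sided exact binomial test. A region was shared when it overlapped a region of the other list by at least 1 bp, and it was paired with the region of largest overlap. The number shared was compared with 1000 random placements of the 11 hpf regions on their own scaffolds, with lengths kept and no overlaps among them. Since open chromatin fills only part of a scaffold, such placements overstate any excess. The mean number expected from independent draws from the numbered set of the 19 hpf list was therefore also computed. A larger set would lower this mean. The draws take each numbered region as equally likely to be listed, and regions more readily listed at both times would raise it. Directions were compared with Fisher's exact test, medians of absolute log2 and of width with two-sided permutation tests of 100000 resamples (adjusted by Benjamini-Hochberg over 6 comparisons), and sizes at both times with Spearman's rho across regions with a permutation p. Clustering was the number of neighbouring regions at most 10 kb apart, against 1000 placements, and the agreement of neighbours' signs was set against 1000 permutations of the signs within a list. The smallest p that 1000 draws can give is 0.002, and 1e-05 is the smallest from 100000. Bootstrap intervals used 10000 draws of whole scaffolds unless stated otherwise.

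The regions named were chosen by a rule: the 5 with the largest absolute log2 per list and direction, the 5 windows of 100 kb per list with the most regions, and the 5 shared regions with the largest overlap. This rule, the tests of each list, of shared regions and of clustering, and most alternatives were fixed before the data were examined. The test of the positive share between the times, the counts by pair of signs, the numbered sets and an absolute log2 of at least 2 or 3 in both lists were added afterwards. The alternatives fixed beforehand were an absolute log2 of at least 1.5, regions within 500 bp merged, scaffolds of at least 1 Mb span, overlap of 50% of both regions, midpoints within 500 bp, placement within 50 kb of each region's own position, shared regions left out, means in place of medians, and neighbours within 5 or 50 kb. The functions were tested on simulated lists with the real numbers, widths and scaffolds. Of 500 planted shared regions among 3897, 500 were recovered, and of 300 planted neighbours, 276 were recovered at 11 hpf (3897 regions) and 290 at 19 hpf (7252 regions). With nothing planted, p was 0.6573 for shared regions and 0.7433 and 0.3497 for clustering at 11 and 19 hpf. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.

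Position relative to genes, regions at listed genes and sequence motifs had been planned. They were not analysed here, since the gene table at hand is of another assembly than the scaffolds of the lists. No region below is therefore placed in an exon, intron or UTR or given a gene name.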

Results

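ATAC-seq was used to ask where chromatin accessibility differed between Activin-treated and control ectodermal explants of amphioxus at 2 times of development. Activin is a signalling protein of the TGF-beta family that acts through SMAD2 and SMAD3, the same route that Nodal uses. Amphioxus is a cephalochordate, and in its embryos Activin or Nodal can turn ectoderm, which otherwise forms epidermis, towards a neural fate. There were 4 groups of 2 libraries, control and Activin (50 ng per mL) at 11 and at 19 hpf. The lists held 3897 differential regions on 708 scaffolds at 11 hpf, covering 2.86 Mb, and 7252 regions on 907 scaffolds at 19 hpf, covering 4.43 Mb. These were 3.48% of at least 111831 numbered regions at 11 hpf and 8.31% of at least 87262 at 19 hpf, both upper limits because each wider set can be larger than its highest listed number. The log2 fold changes are each region's own values from the authors' deposited table, without an error or a number of replicates. Their sign is given as deposited, since the numerator of the ratio is not stated.

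The first comparison was of Activin with control explants at 11 hpf. Negative regions prevailed, with 2660 negative and 1237 positive regions, so that 31.7% were positive (95% interval 30.3 to 33.2%). The split differed from an even one by an exact binomial test over regions, with a log10 p of -117. The median absolute log2 was 2.08 in negative regions, a 4.23-fold difference (quartiles 1.69 to 2.55 on the log2 scale), and 1.85 in positive regions, a 3.59-fold difference (quartiles 1.54 to 2.24). This difference in medians of -0.23 passed the permutation test (adjusted p = 2e-05). The largest positive value was 6.64, in a region of 518 bp on scaffold Sc0000116 from 284804 to 285321. The next were 5.45 on Sc0000112 (546693 to 547204) and 5.16 on Sc0000003 (2283486 to 2283877). None of these 3 overlapped a listed region at 19 hpf. The other 2 of the 5 were also positive at 19 hpf: a region on xpSc0039672 (118398 to 118618) had 4.97 at 11 hpf and 3.33 at 19 hpf, and one on Sc0000102 (59033 to 59356) had 4.65 and 3.33. The most negative values were -7.00 on Sc0000157 (101562 to 101758), -6.93 on Sc0000034 (1356446 to 1356717) and -6.63 on Sc0000300 (124707 to 124854). The next, with -5.55 on Sc0000005 (1910117 to 1910270), was likewise not listed at 19 hpf. The last of these, on Sc0000160 (567739 to 568033), had -5.53 at 11 hpf and -3.12 at 19 hpf. The smallest absolute value listed rose as regions narrowed, and these 5 negative regions were 148 to 295 bp wide.

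At 19 hpf the same comparison gave a longer and more one-sided list. It held 6571 negative and 681 positive regions, so that 9.39% were positive (95% interval 8.73 to 10.1%; exact binomial test over regions, log10 p of -1204). The median absolute log2 was 2.42 in negative regions, a 5.35-fold difference (quartiles 2.06 to 2.96 on the log2 scale), and 2.30 in positive regions, a 4.93-fold difference (quartiles 2.03 to 2.65). The difference in medians was -0.12 (permutation test, adjusted p = 0.000684). It was -0.034 and did not pass the permutation test when regions shared with 11 hpf were left out (p = 0.305). The largest positive values were 7.04 on Sc0000357 (83698 to 83971), 6.94 on xpSc0040052 (3818 to 4311) and 5.94 on Sc0000783 (32958 to 33190). They were followed by 5.81 on Sc0000046 (1799974 to 1800397) and 5.47 on Sc0000002 (520997 to 521722). The most negative values were -9.18 on Sc0000415 (134580 to 134767), -9.06 on Sc0001490 (2251 to 2420) and -8.44 on Sc0000020 (1314218 to 1314772). They were followed by -7.97 on Sc0000059 (1601903 to 1602244) and -7.74 on Sc0000010 (2185872 to 2186105). None of these 10 regions overlapped a listed region at 11 hpf.

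**Figure D1:**
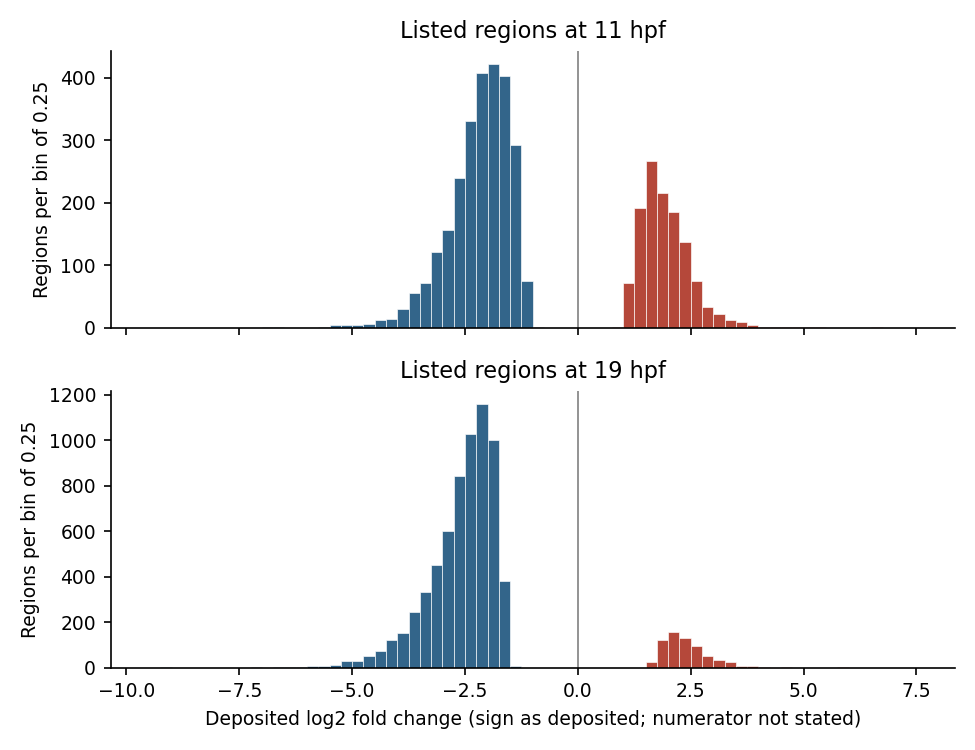
Number of listed regions per bin of 0.25 (y axis) against the deposited log2 fold change between Activin and control explants (x axis), at 11 hpf (upper panel) and 19 hpf (lower panel), with negative values in blue and positive values in red. Of the 3897 regions at 11 hpf 31.7% were positive, and of the 7252 at 19 hpf 9.39%; no region lies near 0, since unlisted regions are not shown.

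The lists of the 2 times were then compared with each other. The share of positive regions was 22.4 percentage points higher at 11 hpf (95% bootstrap interval over scaffolds 20.2 to 24.6; Fisher's exact test over regions, p = 1.75e-186). With an absolute log2 of at least 2 required in both lists, the positive shares were 25.1% at 11 hpf, with 490 positive and 1466 negative regions, and 9.30% at 19 hpf, with 531 positive and 5181 negative regions. The difference in share was smaller at higher thresholds, with 20.4 points at an absolute log2 of at least 1.5, 15.8 at 2 and 9.08 at 3 (95% bootstrap interval over scaffolds 5.18 to 13.4). The median absolute log2 was 2.40 at 19 hpf and 2.005 at 11 hpf, a difference of 0.39 (permutation test, adjusted p = 2e-05). The smallest absolute value listed also differed, at 1.44 against 0.98, and among regions at 2 or more the difference in medians was 0.14 (permutation p = 1e-05, the smallest the resamples can give). Regions were narrower at 19 hpf, with a median of 509 bp (quartiles 324 to 784) against 605 bp (366 to 963), a difference of -96 bp (adjusted p = 2e-05). Among regions at an absolute log2 of 2 or more that difference was -4.5 bp and did not pass the permutation test (p = 0.613). Positive regions were narrower than negative ones at 19 hpf, with medians of 459 and 514 bp (adjusted p = 0.000684). At 11 hpf the medians were 597 and 608 bp, a difference that did not pass the test (adjusted p = 0.523).

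Regions listed at both times were common, and nearly all kept their sign. Of the 11 hpf regions, 1644 overlapped a 19 hpf region, or 42.2% (95% interval 40.6 to 43.8%), and they met 1608 of the 19 hpf regions, or 22.2%. Random placement on the same scaffolds gave a mean of 135 (range 109 to 171), so that the observed number was 12.2 times the mean (permutation p = 0.002, the smallest that the placements can give). Random placement within 50 kb of each region's own position gave a mean of 290.3 and a ratio of 5.66, and independent draws from the numbered set of the 19 hpf list gave 324 and a ratio of 5.08. That set has at least 87262 members, and a larger one would lower the number expected. The number is not a strict upper limit, since the draws take every member as equally likely to be listed. Both times were negative in 1452 regions and both positive in 169, so that 98.6% had the same sign (95% interval 97.9 to 99.1%; Fisher's exact test over regions, p = 3.43e-206). Another 23 were positive at 11 hpf and negative at 19 hpf, and 0 were negative and then positive. Independent draws from that set would give a mean of 200.3 regions negative at both times and 9.65 positive at both. They would give a mean of 93.1 positive then negative and 20.8 negative then positive. Of the negative 11 hpf regions 54.6% (95% interval 52.7 to 56.5%) were negative again at 19 hpf, and of the positive ones 13.7% (11.8 to 15.7%) were positive again. These shares depend on the number of 19 hpf regions of each sign. Relative to the means of the draws, the order was the other way, with ratios of 7.25 (negative at both) and 17.5 (positive at both). The lists came from separate libraries with separate controls.

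The 5 shared regions with the largest overlap were all negative at both times. On Sc0000092 a region from 878949 to 881580 overlapped its 19 hpf counterpart by 2607 bp, with log2 values of -1.66 at 11 hpf and -1.96 at 19 hpf. On Sc0000163 (122282 to 124976) the values were -1.04 and -2.07, and on Sc0000008 (1150519 to 1152935) they were -2.13 and -2.32. On Sc0000499 (4836 to 7217) they were -1.09 and -1.76, and on Sc0000280 (41906 to 44340) -1.73 and -1.99. Over regions negative at both times the medians were -2.12 at 11 hpf and -2.61 at 19 hpf, and 1122 of the 1452 (77.3%) had the larger absolute value at 19 hpf. Over regions positive at both times the medians were 2.06 and 2.21, and 111 of the 169 (65.7%) had the larger value at 19 hpf. The smallest absolute value listed was itself higher at 19 hpf. Across regions, which are not independent replicates, Spearman's rho between the 2 times was 0.43 (Pearson's r 0.43) in the negative and 0.37 (r 0.33) in the positive regions, each with an adjusted permutation p of 1e-05 over 3 correlations.

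**Figure D2:**
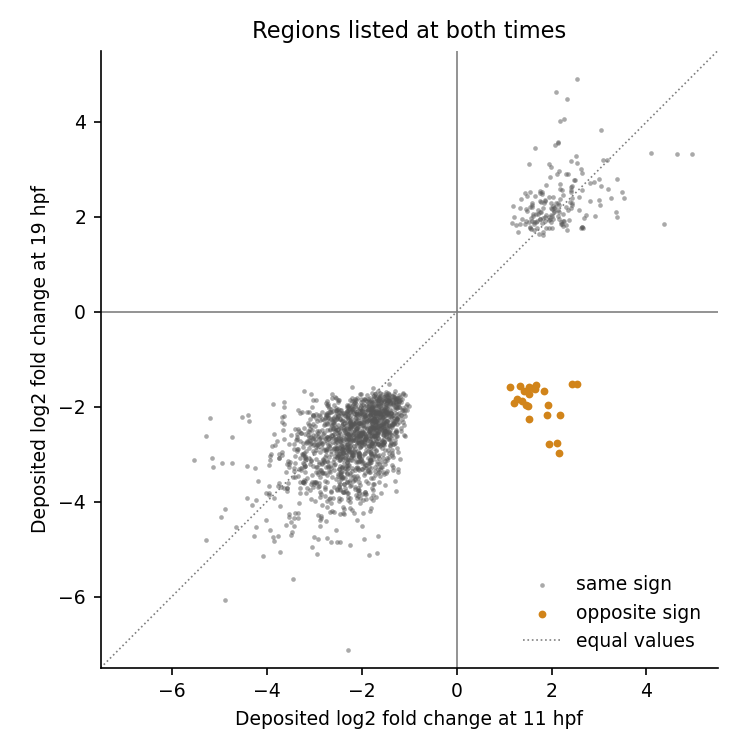
Deposited log2 fold change at 11 hpf (x axis) and at 19 hpf (y axis) of the 1644 regions that overlapped between the lists, 1 point per 11 hpf region, with the dotted line marking equal values. Same-sign regions (grey, 1621) fill the lower left and upper right, and the 23 regions of opposite sign (orange) all lie at positive values for 11 hpf and negative values for 19 hpf.

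Differential regions lay together in the genome, and neighbours shared their sign. At 11 hpf 1204 pairs of neighbouring regions were at most 10 kb apart, against a mean of 415 in random placements, a ratio of 2.90 (permutation p = 0.002). Of these pairs 96.8% had the same sign, against 56.6% with permuted signs (permutation p = 0.002). At 19 hpf there were 2156 such pairs against 1210, a ratio of 1.78 (permutation p = 0.002), and 94.7% had the same sign against 83.0% with permuted signs (p = 0.002). In the numbered sets, which allow for the uneven spread of accessible regions, 872 pairs of consecutive numbers were listed at 11 hpf against 136 in random draws, a ratio of 6.42. At 19 hpf there were 1665 pairs against 604, a ratio of 2.76. Consecutive numbers are another measure than pairs within 10 kb, so the sizes of the 2 kinds of ratio cannot be compared. With regions within 500 bp merged, the ratios within 10 kb were 2.68 at 11 hpf and 1.68 at 19 hpf. Merged regions were not tested in the numbered sets. Against random placements, the ratios for neighbours up to 50 kb apart were 1.27 at 11 hpf and 1.06 at 19 hpf, compared with 2.90 and 1.78 within 10 kb.

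The densest 100 kb window at 11 hpf was Sc0000219 from 200001 to 300000, where all 15 listed regions were positive, with log2 values from 1.23 to 3.59, and all 7 listed at 19 hpf were positive as well. The window on Sc0000137 from 200001 to 300000 held 13 regions at 11 hpf and 15 at 19 hpf, and that on Sc0000000 from 8700001 to 8800000 held 12 and 18, all of them negative. From the first to the last one listed at 11 hpf, the windows on Sc0000219, Sc0000137 and Sc0000000 took in 32, 28 and 27 consecutive numbers. Many numbered regions in these windows were thus not listed. The window on Sc0000000 was the densest at 19 hpf, followed by that on Sc0000137. Windows on Sc0000003 (7100001 to 7200000) and Sc0000017 (1400001 to 1500000) each held 11 negative regions at 11 hpf, and 6 and 7 negative regions at 19 hpf. At 19 hpf the window on Sc0000102 (200001 to 300000) held 9 negative and 2 positive regions. A pair of windows on Sc0000003 held 10 negative regions each. In the first (6300001 to 6400000) they lay among 11 consecutive numbers and had a median log2 of -2.85, and the window held 5 negative regions at 11 hpf. In the other (7500001 to 7600000) they also lay among 11 consecutive numbers and had a median of -3.08, and the window held 0 regions at 11 hpf.

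**Figure D3:**
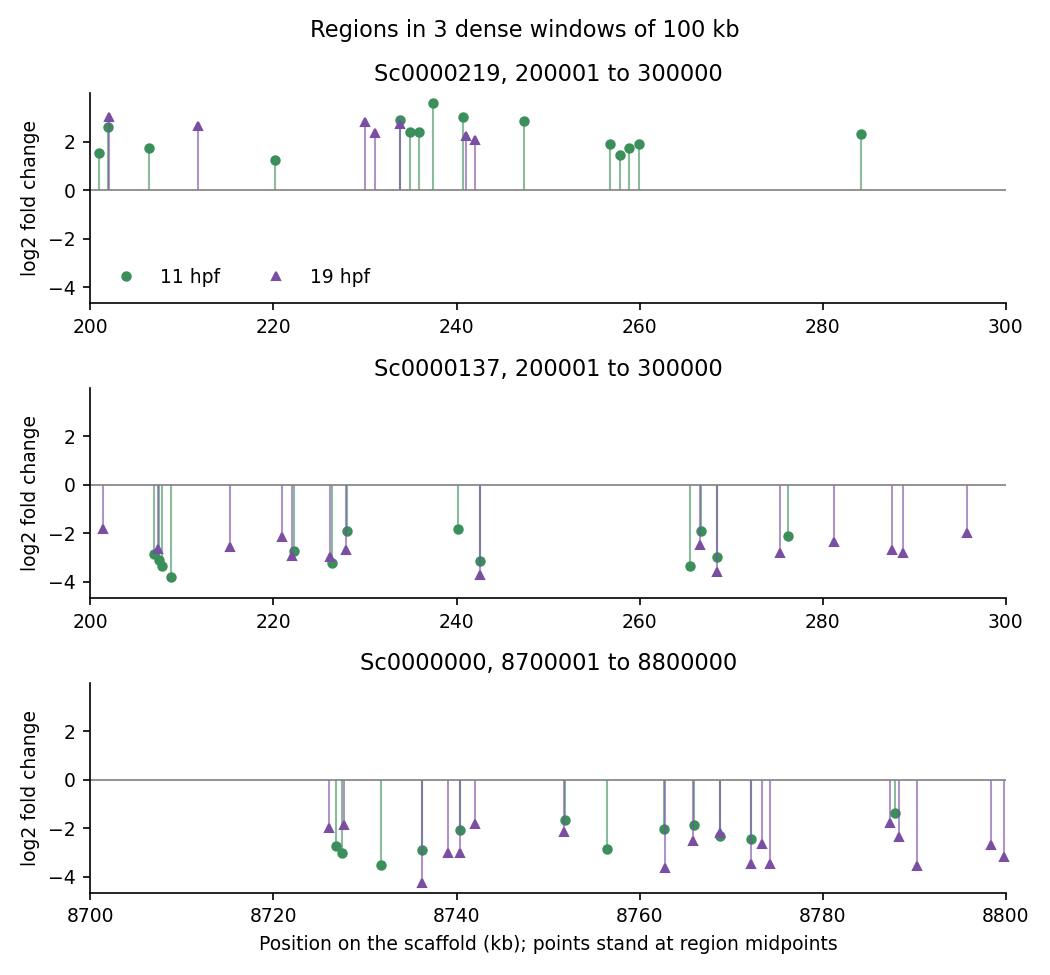
Deposited log2 fold change (y axis) of each listed region against the position of its midpoint in kb (x axis) in the 3 windows of 100 kb with the most regions at 11 hpf, for 11 hpf (green circles) and 19 hpf (purple triangles), each joined to 0 by a line. All 15 regions on Sc0000219 at 11 hpf are positive, and all regions shown on Sc0000137 and Sc0000000 are negative at both times.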

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

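The tests of a single offset and that of closeness to the smallest fold changes were chosen after the results were seen, and the other tests of this part before their results were seen. The comparisons at an absolute log2 of at least 2 and 3 were set up after the lists had been examined. All of these tests run over regions, and none over libraries.

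The positive share was 22.4 percentage points higher at 11 than at 19 hpf, which drew attention because the same comparison differed between the times by Fisher's exact test over regions. The lists' different smallest fold changes are argued against as the whole cause of the difference in share: with an absolute log2 of at least 2 in both lists the difference was 15.8 points (95% bootstrap interval over scaffolds 13.3 to 18.4), more than 50% of its full value. At 3 it was 9.08 points (5.18 to 13.4), above 0 but under 50% of the full value, so part of the difference went with the size of the fold changes. The odds ratio between the times was 4.49 in full, 3.26 at 2 and 2.91 at 3, so how large that part is depends on the scale. The 19 hpf list held fewer positive regions than the 11 hpf list in full (681 against 1237) and at an absolute log2 of at least 1.5 (681 against 972), a threshold that nearly all of the 19 hpf list passes. At 2 it held 531 against 490 and at 3 91 against 57. Negative regions were more numerous at 19 hpf in full (6571 against 2660) and at each of these thresholds, with 5181 against 1466 at 2. One offset added to all log2 values at 19 hpf, as from a scaling of libraries, stays open. At an absolute log2 of 3 or more the positive share was 14.7% at 11 hpf and 5.58% at 19 hpf, and an offset of 0.34 (a 1.27-fold shift) at 19 hpf would bring the second to the first. The match was made at this threshold alone, where the difference was 9.08 points against 15.8 at 2. With 0.34 added, at most the 681 listed positive regions could reach 2 at 19 hpf. More than 50% of the 6571 negative ones, with a median absolute log2 of 2.42, would still reach it. Among listed regions the positive share at 2 would thus stay under the 25.1% of 11 hpf. This does not decide, since positive values near the smallest listed (1.53) would then count and unlisted regions could add to them. Such an offset cannot be told apart from a change in the tissue, because only 19.1% of the top quartile of positive 11 hpf regions were listed as positive at 19 hpf and the listing then sets their values. The later stage, which the design names, also stays open and untested.

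The other result to look at again is the set of 23 regions that were positive at 11 hpf and negative at 19 hpf, on 20 scaffolds and over 21 distinct 19 hpf regions, with 0 regions the other way. They drew attention because the direction differed between the times, and the excess of this order over the other was not tested. Independent draws from the numbered set would give a mean of 93.1 regions in this order and 20.8 in the other. The 23 were thus fewer than such draws give, and the make-up of the lists by itself favours this order. Overlap of the edges of neighbouring regions is argued against as the whole cause, since 65.2% of the 23 (95% interval 42.7 to 83.6%) overlapped by 50% of both lengths, against 79.5% of same-sign regions (Fisher's exact test, p = 0.117). Changes close to the smallest fold changes listed are a candidate explanation for the values at 19 hpf. Of the 23, 73.9% lay in the lowest quartile of absolute log2 among negative regions at 19 hpf, against 14.6% of regions negative at both times. The latter were picked for recurring and do not stand for all negative regions. Width was not allowed for, and the median absolute log2 at 19 hpf was 2.20 in the widest quartile against 2.59 in the narrowest. A low value in a wide region need not be a marginal call. At 11 hpf 47.8% of the 23 (95% interval 26.8 to 69.4%) lay in the lowest quartile of positive values, so the positive values at 11 hpf are less clearly covered. One offset at 19 hpf that alone made the whole change in these regions is argued against. From 11 to 19 hpf their log2 changed by -5.12 to -2.70, with a median of -3.41. Regions negative at both times changed by a median of -0.53 (95% bootstrap interval over regions -0.56 to -0.49), and the listing did not keep them from falling as far. Part of the gap was built in, however. No positive value at 11 hpf was under 0.98, and no absolute negative value at 19 hpf was under 1.44. Only regions that fell far could therefore be among the 23. Whether a smaller offset adds to the single order of signs was not tested, and the later stage stays open. Ranked by the smaller of the absolute values at both times, the first regions, named after their values were seen, were on Sc0000019 (3223617 to 3224564), with 2.18 and -2.18, and on Sc0000182 (12023 to 12259), with 2.15 and -2.97.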

How the results depend on the processing

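The alternatives with an absolute log2 of at least 2 or 3 and with draws from the numbered set were chosen after seeing the data, and the others before. Of 65 alternative values for 17 results, 57 kept their direction and their side of the threshold or, for counts, stayed within 1.5 times. For 3 of these 57 the outcome was fixed in advance: the count of shared regions under another random placement, and the count and positive share at 19 hpf at an absolute log2 of at least 1.5, which leaves out 7 regions of that list. Without them 54 held, including the ratio of shared regions with draws from the numbered set, for which no p was computed. For that ratio the observed 1644 regions lay above the 95% range of such draws, 291 to 357. On scaffolds of at least 1 Mb covered span, which holds fewer regions by construction, 2308 regions remained at 11 hpf and 4579 at 19 hpf. An absolute log2 of at least 2 left 1956 regions at 11 hpf by construction, and of at least 3 left 389 at 11 hpf and 1632 at 19 hpf. The difference in median absolute log2 between positive and negative regions at 19 hpf was -0.034 with shared regions left out and no longer passed the test (the cause was not tested). The width difference between the times was -4.5 bp at an absolute log2 of at least 2 and no longer passed the test (the cause was not tested). The width difference between positive and negative regions at 11 hpf, which passed no test, was 2.51 bp by means against -11 bp by medians. Over its alternatives the ratio of shared regions to those expected ranged from 5.08 to 24.7. The same-sign share was 98.8 and 98.9% in its alternatives, against 98.6% in the main setting. No paired analysis was possible because the lists hold no values per library, and a replicate block and leaving out replicates were not run for the same reason. The alternatives for gene positions, listed genes and motifs were not run either. With no p-values in the lists, an absolute log2 of at least 1.5 stood for the stricter threshold and was stricter in effect at 11 hpf alone. Depth per library is unknown, so regions missing from a list cannot be read as equal between groups.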

Other observations

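The share of positive regions by scaffold span was noticed in these data, and its tests were chosen after that but before their results were seen. The tests of recurrence by size and of neighbouring positions were set before their results were seen.

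Regions in the highest quartile of absolute log2 at 11 hpf recurred with the same sign at 19 hpf more often than those in the lowest. Among positive regions the share rose from 5.48% (95% interval 3.23 to 8.64%) in the lowest quartile of log2 to 19.1% (14.9 to 23.9%) in the highest, with Fisher's exact p = 1.65e-07. Among negative regions it was 52.6% (48.8 to 56.5%) in the lowest and 59.1% (55.3 to 62.9%) in the highest quartile (Fisher's exact p = 0.0203). It was 51.3% in the second and 55.3% in the third quartile, so the rise was not steady. Both p-values take regions as independent, although neighbouring regions lay together and shared their sign. Regions of the highest quartile were narrower, with medians of 421 bp (positive) and 437 bp (negative) against 961 and 938 bp, so they had less length in which to overlap. The lowest quartiles at 11 hpf spanned 0.98 to 1.54 (positive) and 0.98 to 1.69 (negative). The smallest absolute values listed at 19 hpf were 1.53 and 1.44. Most regions of the lowest positive quartile could thus recur only with a larger value at 19 hpf. How much of the trend the listing alone would give was not tested.

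Regions listed at 11 hpf alone had a 19 hpf region of the same sign nearby more often than randomly placed regions did, though most of them had none within 10 kb. Of 1208 such negative regions, 47.1% (95% interval 44.3 to 50.0%) had a negative 19 hpf region within 10 kb, against a mean of 31.7% and a highest of 35.7% in 1000 placements within 50 kb. Of 1045 such positive regions 11.9% (9.97 to 13.98%) had a positive one, against a mean of 7.44% and a highest of 9.57%. How much of this excess grouping of accessible regions in general would give was not tested.

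Positive regions were more frequent on scaffolds of short covered span. At 11 hpf 38.9% of 1589 regions on scaffolds under 1 Mb were positive against 26.8% of 2308 on longer ones, a difference of 12.1 points (95% bootstrap interval over scaffolds 7.09 to 17.1). At 19 hpf the shares were 13.3% and 7.12%, a difference of 6.16 points (3.73 to 8.53). On scaffolds under 100 kb they were 47.6% and 17.7%, and on those over 4 Mb 24.3% and 5.56%. The share also differed by the prefix of the scaffold name. At 11 hpf it was 61.4% on xpSc, 41.1% on xfSc and 30.9% on Sc scaffolds, and at 19 hpf 18.1%, 18.6% and 9.00%. Whether span or this naming goes with the share was not tested. Region width is argued against as the whole cause, since weighting 5 classes of width equally left 12.1 points at 11 hpf (7.16 to 17.1) and 6.26 at 19 hpf (3.81 to 8.64). That a few scaffolds hold much of the excess stays open: without the 10 short scaffolds with the most positive regions the difference was 8.93 points (4.27 to 13.7) at 11 hpf and 4.27 points (2.19 to 6.28) at 19 hpf, above 0 in both but with intervals that reach below 50% of the full value. These 10 scaffolds were picked by their positive regions in the same list, and from the short scaffolds alone. Some fall in the difference was therefore built in, and the fall itself does not speak for this explanation. Whether reads shared between near-identical sequences on short scaffolds play a part was not tested, and no biological explanation was tested.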
